A study of Mus musculus with 32 samples.

How the data were processed

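The samples were mouse RNA from normal urothelium, the epithelium that lines the bladder, and from BC57, a mouse bladder cancer cell line. Per the labels' protocols, urothelium came from 9 mice, and each piece of tissue and the pellet of cultured cells were divided into a part that was fresh frozen (FF) and a part that was fixed in formalin for 24 h and embedded in paraffin (FFPE). RNA of the FFPE parts was extracted from 10 sections of 5 µm. Whether RNA of the 9 mice was pooled is not given in the sources used here.

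Each of these 4 kinds of RNA (urothelium or BC57, FF or FFPE) was amplified with different kits and amounts, labelled with biotin and hybridized to an array. The WT Pico kit was used with 2 ng and 0.5 ng of FF or FFPE RNA, in triplicate. The SensationPlus kit was used with 50 ng of FFPE RNA and the WT Plus kit with 100 ng of FF RNA, both in duplicate. The series names FF RNA with 100 ng and WT Plus as its reference. This gave 32 arrays in 12 groups. Kit and input were tied outside WT Pico: 100 ng was run with WT Plus and 50 ng with SensationPlus, so a difference between these and a WT Pico group is a difference of kit and input together, and FFPE 50 ng against FF 100 ng differs in fixation, kit and input.

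The deposited table holds log2 expression values that the authors made with RMA, which corrects background, normalizes arrays and summarizes probes, using the affy package, per the submitters' processing notes. Versions of both, the array design, the genome build of the probe annotation and whether the arrays were normalized together are not given in the sources used here. The table has 21237 probe sets for 32 arrays, with values from 1.23 to 13.22 and none below 0. No pair of arrays held identical values. Each probe set carries an Ensembl mouse gene identifier. The files do not pair these identifiers with gene names, and the table of reference genes at hand gave names to 0 of them. For this reason tests ran on all probe sets, 28 gene lists fixed before the data were examined were not tested, no gene list result is reported here, and genes are given by identifier for the 2 largest rises and the 2 largest falls in the reference, the first of those that the rule fixed beforehand would name. That rule took probe sets past the threshold by size of change, largest first.

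Array data hold no read depth, and the number of arrays limits the precision. The series' design speaks of 4 samples run in duplicate or triplicate, and nothing says that the arrays of a group came from separate animals or cultures; they were treated as repeat amplifications. The p-values therefore measure only the spread between these arrays, read here as technical, and a difference between BC57 and urothelium is a difference between these particular RNA samples.

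Differences were tested in R 4.3.3 with limma 3.58.1 on the deposited log2 values (lmFit, then eBayes with an intensity trend, 2-sided), with Benjamini-Hochberg adjustment over the 21237 probe sets. A probe set was called at an adjusted p under 0.05 and an absolute log2 change of at least 1, which is a fold of 2. The BC57 minus urothelium change was fitted in each of the 6 conditions on the arrays of that condition alone. Condition contrasts and the difference of the BC57 minus urothelium change between conditions (the interaction) were fitted on the 4 groups of the 2 conditions compared. A condition contrast was the mean of the changes within urothelium and within BC57. Recall is the percentage of probe sets called in the reference that were called in the same direction in the condition. The ratio of changes is the median, over the reference calls, of the log2 change in the condition divided by that in the reference. Since those probe sets were picked by their reference values, a ratio slightly under 1 arises from noise in the reference alone. Errors of recall, r, ratio and counts are jackknife standard errors from leaving out 1 array at a time. In conditions with duplicates this leaves a single array in a group, which is assumed to vary like the others. The errors pool the arrays of all groups used and are rough, and a value can lie outside its own leave-out range. At FF 0.5 ng, r was 0.953 with all arrays and 0.947 to 0.951 without single arrays. Correlations were taken over probe sets, which are not independent replicates, so they carry no p-value. Differences between arrays in the spread and median of all values were tested by exact 2-sided permutation.

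Replicate numbers did not pair arrays where at least 3 pairs could be checked: over 12 such comparisons, 0 had every correlation of same-numbered arrays' deviations over 0.1. Comparisons with 2 pairs passed 0.1 only among duplicates. They were BC57 minus urothelium at FFPE 50 ng (0.155) and FFPE 50 ng minus FF 100 ng in urothelium (0.139) and BC57 (0.132). The fits therefore had no replicate block.

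The steps were tested on simulated values that kept the replicate spread of the real arrays, with 200 probe sets changed by 1.5-fold, 2.5-fold or 4-fold. At 2.5-fold, the BC57 minus urothelium fit recovered 87.9% of changed probe sets in FF 100 ng, 95.1% in FF 2 ng, 87.9% in FF 0.5 ng, 50.8% in FFPE 50 ng, 91.3% in FFPE 2 ng and 78.1% in FFPE 0.5 ng, with at most 1 false call in each. The noise in this simulation was Gaussian, and 200 of the 21237 probe sets changed. In the real fits 3468 to 12097 passed the adjusted p, so the adjustment was stricter in the simulation. At FFPE 50 ng the 50.8% equalled the share past the adjusted p, and 77.3% were recovered at 4-fold. These percentages therefore do not rank the conditions by power in the real fits. The simulated folds were also folds of the measured values. Real changes were measured smaller in FFPE WT Pico arrays than in the reference, at median ratios of 0.479 (2 ng) and 0.373 (0.5 ng). The percentages are thus no measure of how many reference changes of that size such arrays recover.

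Alternatives fixed before the data were examined were a fit on all 32 arrays, a restriction to probe sets brighter than the median, centring each array on its median, quantile normalization over all arrays, eBayes without the trend, array weights, the adjusted p alone, the replicate number as a block, and leaving out each array in turn. The use of 2 of the 3 arrays of each WT Pico group was added after the data were seen. The planned choice between 1 probe set per gene and all probe sets was void, because each identifier has 1 probe set. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.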

Results

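Expression in normal mouse urothelium and in the BC57 bladder cancer line was measured on 32 arrays, to ask how low RNA input, amplification kit and formalin fixation change what an array reports about the same RNA sources. There were 6 conditions for each cell type: FF RNA at 100 ng (WT Plus, n = 2, the reference), 2 ng and 0.5 ng (WT Pico, n = 3 each), and FFPE RNA at 50 ng (SensationPlus, n = 2), 2 ng and 0.5 ng (WT Pico, n = 3 each). All values are log2 RMA values of 21237 probe sets, 1 for each Ensembl mouse gene identifier. The series' design describes the replicates as repeats of a sample, so the errors are read as technical.

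The main axes of the data went with cell type and with preservation, the latter not apart from kit and input. The first principal component held 42.6% of the variance and the second 36.2%. In the 24 WT Pico arrays, where the design is balanced, preservation took 46.3% of the sum of squares, cell type 36.1%, their interaction 6.46%, the 4-fold difference of input 1.16%, and the spread between replicates 7.86%. Urothelium and BC57 arrays from FF RNA lay in separate groups whatever the kit or input. On both components, FFPE 50 ng arrays lay between the FF and the FFPE WT Pico arrays of their cell type.

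**Figure D1:**
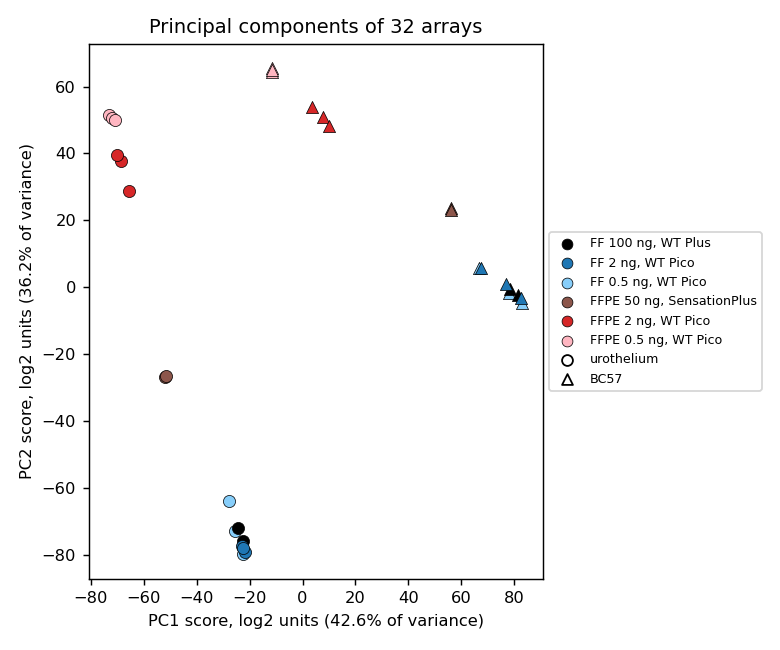
Scores of the 32 arrays on the first component (42.6% of the variance, x axis) and the second (36.2%, y axis), both in log2 units; circles are urothelium, triangles BC57, colours the 6 conditions, and each point is 1 array. FF arrays of a cell type lie together, FFPE 50 ng arrays lie apart from them, and FFPE WT Pico arrays lie farther away in the same general direction.

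Correlations between replicates reached lower values in FFPE than in FF groups. Pairwise correlations over probe sets within a group ran from 0.992 to 0.997 in FF and from 0.964 to 0.993 in FFPE groups. The root mean square of the SD between replicates was 0.11 in BC57 and 0.11 in urothelium at FF 100 ng, and 0.17 in both at FF 0.5 ng. It was 0.16 in BC57 and 0.15 in urothelium at FFPE 50 ng, and 0.22 and 0.25 at FFPE 0.5 ng.

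FFPE RNA gave a narrower range of values with WT Pico. The SD over probe sets of a urothelium array was 1.42 ± 0.04 (SD, n = 6 arrays) in FFPE and 1.95 ± 0.03 (n = 6) in FF (exact permutation p = 0.00217). In BC57 arrays it was 1.55 ± 0.06 and 1.96 ± 0.04 (n = 6 each, exact permutation p = 0.00217). Array medians were higher in FFPE, at 5.77 ± 0.02 against 5.37 ± 0.03 in urothelium and 5.68 ± 0.05 against 5.35 ± 0.05 in BC57 (n = 6 each, exact permutation p = 0.00217 in both). This p is the smallest that 924 relabelings allow, and each of these 4 comparisons stays at 0.00217 after Benjamini-Hochberg adjustment. FFPE and FF values did not overlap in any of them.

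The shift depended on brightness. Against the reference, the median change of the dimmest quintile of probe sets at FFPE 2 ng was 0.72 in urothelium and 0.50 in BC57, and that of the brightest quintile was -0.60 and -0.40. At FFPE 0.5 ng the dimmest quintile stood 0.92 and 0.69 higher and the brightest changed by -0.65 and -0.54. SensationPlus at FFPE 50 ng gave 0.27 and 0.18 for the dimmest, and -0.33 and -0.12 for the brightest quintile. In FF WT Pico arrays every quintile median was within 0.1 of the reference.

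**Figure D2:**
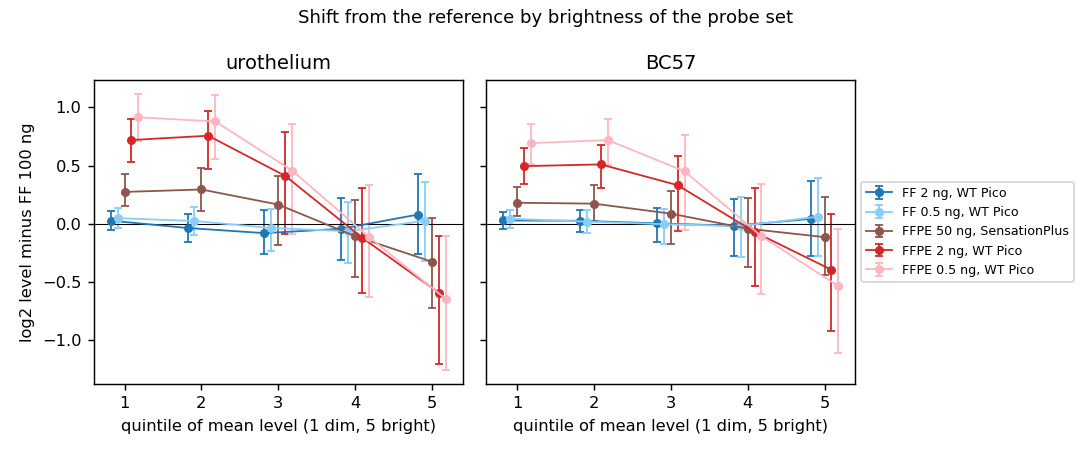
Median log2 level minus the reference level (y axis) by quintile of mean level over all arrays (x axis, 1 dimmest, 5 brightest) in urothelium (left) and BC57 (right); colours are conditions and bars run from the lower to the upper quartile of the probe sets. FFPE WT Pico medians fall from 0.72 in the dimmest to -0.60 in the brightest quintile of urothelium at 2 ng, and FF medians stay near 0.

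In the reference, BC57 differed from urothelium at 3273 probe sets, 15.4% of those measured, with 1711 higher and 1562 lower in BC57 (limma, n = 2 each). The largest fitted rise was ENSMUSG00000024512, at 11.55 ± 0.02 in BC57 and 2.86 ± 0.04 in urothelium (SD, n = 2), a log2 change of 8.68 ± 0.06 (SE, limma adjusted p = 1.15e-07). ENSMUSG00000056457 had a fitted change of 7.65 ± 0.15 (limma adjusted p = 4.24e-07), with urothelium at 2.02 ± 0.32 (SD). These urothelium levels lay near or below the median of the dimmest quintile there, 2.72, and detection calls were not used here, so both probe sets may be at background in urothelium and the sizes and order of their changes depend on it. The largest fitted falls were ENSMUSG00000043461, with a change of -7.83 ± 0.07 (limma adjusted p = 1.15e-07), and ENSMUSG00000056293, with -7.71 ± 0.12 (limma adjusted p = 2.55e-07). Both were bright in urothelium, at 11.77 and 11.08, and dim in BC57, at 3.94 and 3.37, so their sizes may depend on background too. By size, 2291 of the called probe sets changed by 2-fold to 4-fold, 643 by 4-fold to 8-fold and 339 by more. Adjusted p alone passed 10758 probe sets.

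FF RNA at low input gave a BC57 minus urothelium contrast close to the reference. At 2 ng, 3180 probe sets were called (1621 higher, 1559 lower in BC57), and 2713 of them were shared with the reference in the same direction, where independent lists would share 245. At 0.5 ng, 3184 were called (1723 higher, 1461 lower), with 2696 shared and 246 for independent lists. The majority direction depended on the scaling. As deposited, after centring and after quantile normalization, 52.3%, 56.2% and 48.7% of the reference calls were higher in BC57. These were 51%, 51.7% and 46.4% at 2 ng, and 54.1%, 57% and 48.4% at 0.5 ng. Recall of the reference calls was 82.9% ± 3.09 at 2 ng and 82.4% ± 2.63 at 0.5 ng, a difference within the jackknife SE. The changes correlated with those of the reference at r = 0.954 and 0.953 over probe sets (Spearman's rho 0.879 and 0.876), and the median ratio of changes was 0.943 ± 0.03 and 0.942 ± 0.03. The 2 low inputs resembled each other more than the reference: 90.4% of the 2 ng calls were called at 0.5 ng, at r = 0.981.

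Single probe sets departed from the reference. The BC57 minus urothelium change itself differed at 161 probe sets for 2 ng (82 smaller, 79 larger than in the reference) and at 138 for 0.5 ng (90 smaller, 48 larger). Of the 161, 59.0% had a more positive change at 2 ng, and 46.8% of 158 after centring; among probe sets brighter than the median 97 were called. ENSMUSG00000056457 changed by 4.60 ± 0.15 at 2 ng and 4.96 ± 0.16 at 0.5 ng, against 7.65 in the reference. ENSMUSG00000024512 changed by 8.83 ± 0.08 and 8.71 ± 0.11, ENSMUSG00000043461 by -7.72 ± 0.08 and -7.43 ± 0.10, and ENSMUSG00000056293 by -7.47 ± 0.06 and -7.55 ± 0.16 (SE, n = 3 each).

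FFPE RNA at 50 ng with SensationPlus gave as many calls as the reference. There were 3329 called probe sets, 1952 higher and 1377 lower in BC57. The percentage higher was 58.6% as deposited, 65.1% after centring and 51.0% after quantile normalization. Of the 3329, 2603 were shared with the reference in the same direction (259 for independent lists). Recall was 79.5% ± 1.35, 78.2% ± 2.58 of its own calls were reference calls, and the changes correlated at r = 0.918 (rho 0.811). The median ratio was 0.892 ± 0.01, at 0.978 for probe sets higher in BC57 and 0.816 for those lower. The change differed from that in the reference at 325 probe sets, 202 of them smaller and 123 larger; 175 were called among probe sets brighter than the median. The named probe sets were all called, at 8.08 ± 0.16 for ENSMUSG00000024512, 6.95 ± 0.14 for ENSMUSG00000056457, -7.88 ± 0.10 for ENSMUSG00000043461 and -6.13 ± 0.12 for ENSMUSG00000056293 (SE, n = 2 each).

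FFPE RNA at low input with WT Pico gave fewer calls and smaller changes. At 2 ng, 1562 probe sets were called (1049 higher, 513 lower in BC57), and at 0.5 ng, 955 (647 higher, 308 lower). The split of directions depended on the scaling: 67.2% of the calls were higher in BC57 at 2 ng as deposited, 76.8% after centring and 58.0% after quantile normalization, and at 0.5 ng 67.7%, 73.2% and 60.7%. Recall was 38.0% ± 1.35 at 2 ng and 24.9% ± 1.12 at 0.5 ng. Of the calls made, 79.6% ± 4.91 and 85.2% ± 3.03 were also reference calls in the same direction, 1244 and 814 probe sets where independent lists would share 122 and 74.8. Correlations with the reference were r = 0.776 (rho 0.647) and r = 0.745 (rho 0.624). The median ratio of changes was 0.479 ± 0.02 at 2 ng and 0.373 ± 0.01 at 0.5 ng, and 98.8% and 97.5% of the reference calls kept their sign. After quantile normalization over all arrays, the ratio was 0.669 at 2 ng and 0.566 at 0.5 ng, and recall was 54.0% and 41.2%. Both refer to the 2632 probe sets called in the normalized reference. The calls were 2050 at 2 ng and 1452 at 0.5 ng.

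**Figure D3:**
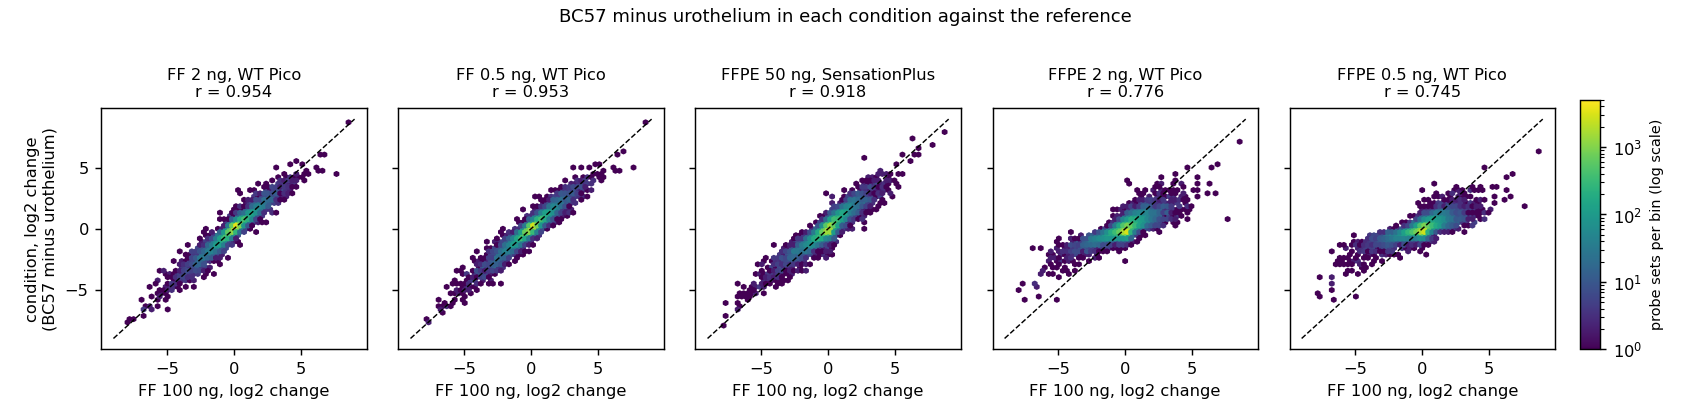
Log2 change, BC57 minus urothelium, in the reference (x axis) against each other condition (y axis), 1 panel per condition; colour gives the number of probe sets in a bin on a log scale and the dashed line marks equal changes. The FF panels follow the line (r = 0.954 and 0.953), and FFPE WT Pico changes lie flatter (median ratios 0.479 and 0.373).

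Large changes were found again more often than small ones. Of the 339 probe sets changed over 8-fold in the reference, 100% were called at FF 2 ng and FF 0.5 ng, 99.7% at FFPE 50 ng, 88.5% at FFPE 2 ng and 70.8% at FFPE 0.5 ng. Of the 2291 changed by 2-fold to 4-fold, 76.0%, 75.4%, 71.7%, 25.1% and 14.7% were called in the same order. The sizes of large changes were not better kept in FFPE WT Pico arrays. From the smallest to the largest class, the median ratio was 0.495, 0.445 and 0.458 at FFPE 2 ng. At FFPE 0.5 ng it was 0.380, 0.365 and 0.352. With similar ratios, a small change falls under the fixed 2-fold threshold more easily than a large one. At FFPE 2 ng, recall was 20.2% of the 263 reference calls in the dim tertile of probe sets and 47.3% of the 1733 in the bright tertile. On the deposited values, probe sets lower in BC57 were recalled less often than those higher in BC57, at 29.5% against 45.8% at FFPE 2 ng and 18.4% against 30.7% at FFPE 0.5 ng, a difference that was not tested.

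**Figure D4:**
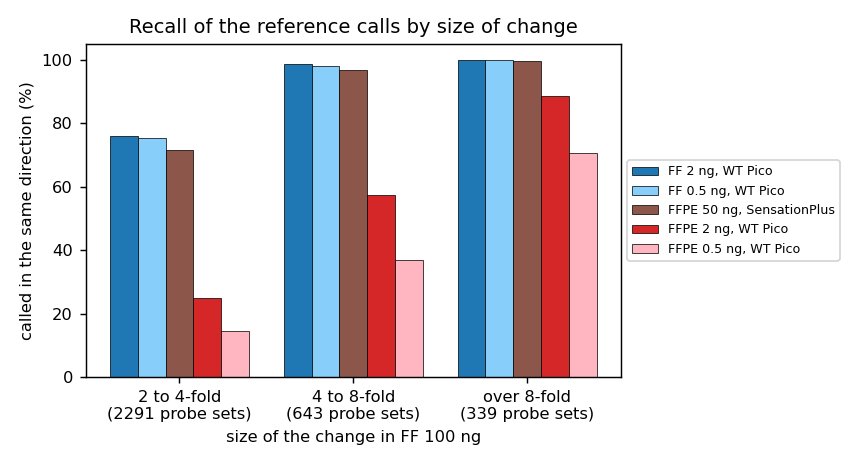
Percentage of reference calls that were called in the same direction (y axis, from 0) by size of the change in the reference (x axis, with the number of probe sets), 1 bar per condition. Bars for changes over 8-fold run from 70.8% to 100%, and bars for changes of 2-fold to 4-fold from 14.7% to 76.0%.

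The test of the difference gave 1343 probe sets whose BC57 minus urothelium change differed between FFPE 2 ng and the reference, 1235 of them smaller at FFPE 2 ng and 108 larger. For FFPE 0.5 ng there were 1584, with 1537 smaller and 47 larger. These counts were 670 and 723 after quantile normalization. At FFPE 2 ng ENSMUSG00000024512 changed by 7.11 ± 0.12, ENSMUSG00000043461 by -5.10 ± 0.20 and ENSMUSG00000056293 by -4.37 ± 0.15, and at FFPE 0.5 ng by 6.51 ± 0.14, -5.33 ± 0.15 and -3.83 ± 0.15 (SE, n = 3 each, all called). ENSMUSG00000056457 was not called at FFPE 2 ng, with 0.84 ± 0.48 (limma adjusted p = 0.192) and 0.25 to 1.16 without single arrays. At FFPE 0.5 ng it was called, with a change of 1.91 ± 0.39 (limma adjusted p = 0.0169). That last call was lost without urothelium replicate 1 (1.90, limma adjusted p = 0.0511), urothelium replicate 3 (1.89, 0.0507) or BC57 replicate 3 (1.93, 0.0543).

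Across conditions, 4601 probe sets were called in at least 1 condition and 681 in all 6 with the same direction, 429 higher and 252 lower in BC57. All 3 FF conditions shared 2564 calls. Of these, 2207 were also called at FFPE 50 ng in the same direction and 330 in no FFPE condition. Another 683 were called in some FFPE condition and in no FF condition. Opposite directions in any 2 conditions were called for 2 probe sets.

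The effect of condition on the levels themselves was tested as the mean change of both cell types. WT Pico against WT Plus in FF RNA changed 695 probe sets at 2 ng (323 higher, 372 lower) and 669 at 0.5 ng (254 higher, 415 lower). Within single cell types the 2 ng contrast called 857 in urothelium and 779 in BC57, 455 of them in both and in the same direction. After quantile normalization the 0.5 ng count was 445. Kit and input differ together here.

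With WT Pico at the same input, FFPE minus FF gave 2275 probe sets at 2 ng (916 higher, 1359 lower) and 3862 at 0.5 ng (2165 higher, 1697 lower). FFPE at 50 ng with SensationPlus against the reference gave 1026 (413 higher, 613 lower; n = 2 per group against 3), and there kit and input changed along with fixation. The median of all probe sets was itself shifted, by 0.32 at 2 ng, 0.39 at 0.5 ng and 0.12 at 50 ng, and the split of directions depended on it. Relative to that shift, with arrays centred on their medians, 9.31% of the calls were higher in FFPE at 2 ng, 11.6% at 0.5 ng and 28.5% at 50 ng, against 40.3%, 56.1% and 40.3% as deposited. Quantile normalization gave 1281 calls at 2 ng, 1901 at 0.5 ng (44.2% higher) and 676 at 50 ng. The 0.5 ng count was 2049 among probe sets brighter than the median.

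The WT Pico changes with fixation at the 2 inputs share no arrays but come from the same RNA sources. They correlated at r = 0.971 over probe sets, with 2060 calls in the same direction where independent lists would share 202. Any difference between these particular FF and FFPE RNA samples is common to both, so this shows repeatable measurement and no repeat of the fixation. After quantile normalization r was 0.941, with 1110 shared and 58.1 for independent lists. The 2 ng WT Pico contrast and FFPE 50 ng minus the reference, which also differs in kit and input, correlated at r = 0.571, with 428 calls shared, 30 opposite and 57.0 for independent lists. After quantile normalization these were r = 0.461, 232, 29 and 20.4. Within FFPE RNA, WT Pico at 2 ng against SensationPlus at 50 ng changed 1262 probe sets (536 higher, 726 lower); the median shift was 0.17, and 19.4% of the calls were higher after centring against 42.5% as deposited.

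FFPE minus FF called more probe sets in urothelium than in BC57. At 2 ng, 4814 were called in urothelium (2637 higher, 2177 lower in FFPE) and 1754 in BC57 (578 higher, 1176 lower), with 1164 called in both in the same direction. These directions depended on the shift of the arrays: 54.8% of the calls in urothelium and 33.0% in BC57 were higher as deposited, 11.3% of 4321 and 10.1% of 2456 after centring, and 43.0% and 44.0% after quantile normalization. The change differed between the cell types at 1477 probe sets. At 0.5 ng the counts were 6007, 3236 and 1573, and at 50 ng against the reference 1486, 1000 and 325. After centring, the 0.5 ng counts were 4482 in urothelium and 3779 in BC57. After quantile normalization the counts in urothelium, in BC57 and for the difference were 2402, 929 and 781 at 2 ng, 2889, 1574 and 755 at 0.5 ng, and 1053, 664 and 220 at 50 ng.

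A 4-fold lower input within WT Pico changed few probe sets by 2-fold. In FF RNA, 0.5 ng against 2 ng called 2 probe sets, both lower, and 1871 passed an unadjusted p under 0.05 where chance gives 1062; after quantile normalization the 2 became 0. In FFPE RNA, 3 were called, with 5710 at an unadjusted p under 0.05, and 9 were called in a fit on all 32 arrays. The median of all probe sets was shifted by 0.07 in FFPE and 0.0041 in FF. By cell type the calls were 4 in urothelium and 1 in BC57 for FF, and 0 and 4 for FFPE. For FF, 2075 in urothelium and 1054 in BC57 passed the unadjusted p, the latter no more than the 1062 of chance. For FFPE these were 3058 and 5049. No probe set was called by limma for a difference of this input effect between cell types, in FF or FFPE, with 1183 and 2111 at an unadjusted p under 0.05. Leaving out single arrays changed the FFPE count of 3 to between 0 and 3, and it was 0 without any 1 of 6 arrays (urothelium 2 ng replicates 1 and 2, BC57 2 ng replicates 1 to 3 and BC57 0.5 ng replicate 3). It was 1 without urothelium 0.5 ng replicate 1 or BC57 0.5 ng replicate 1.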

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

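Of the tests in this part, those of low input alone, of fixation alone, of a difference between fixed and frozen parts and of the ratio of calls between cell types, and all regroupings of arrays, were chosen after the results were seen; the range over single arrays left out was added to the tests on quantile-normalized values after their first values were seen, and 1 of them, on the count of differing probe sets, then decided nothing by itself. The counts given next stood out because the change with condition differed between urothelium and BC57 in a test of the difference. Against the reference this is the same test as that of the BC57 minus urothelium change above. It does not separate a response of a cell type from smaller changes in general.

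Against the reference, the change with condition differed between the cell types at 161 probe sets for FF 2 ng, 138 for FF 0.5 ng, 325 for FFPE 50 ng, 1343 for FFPE 2 ng and 1584 for FFPE 0.5 ng. It differed at 1477 probe sets for FFPE minus FF at 2 ng, at 1573 for FFPE minus FF at 0.5 ng (781 and 755 after quantile normalization) and at 906 for FFPE 2 ng minus FFPE 50 ng. Of the 1343 and 1584 against the reference, 1201 and 1485 were also reference calls, and 1235 and 1537 had a smaller BC57 minus urothelium change than there.

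The BC57 minus urothelium changes were smaller in FFPE WT Pico arrays than in the reference, with 1235 of the 1343 differing probe sets smaller at FFPE 2 ng. Low input alone was argued against by FF WT Pico arrays at the same inputs, whose lower median ratio to the reference was 0.942, and fixation alone, whatever the kit and input, by the FFPE SensationPlus arrays at 0.892 (0.888 to 0.902 without single arrays). A difference between the fixed and frozen parts of the tissue or pellet alone was argued against by the same 0.892, if both kits received RNA of the same fixed part. A narrower distribution of values that quantile normalization can undo was argued against as the whole cause. After quantile normalization the ratio at FFPE 2 ng rose from 0.479 to 0.669 (0.661 to 0.674 without single arrays). The reference was called anew on the normalized values, at 2632 probe sets against 3273. The 2 ratios are therefore medians over different probe sets, and the reference changes were altered as well as those at FFPE 2 ng. The ratio of 0.669 stayed under the bound of 0.7 fixed beforehand, so the narrower distribution may account for part. Quantile normalization cannot restore differences between probe sets lost before it, so a loss of that kind was not tested. Open and untested is fixation, or the quality of the fixed RNA, which was not measured here, in combination with the kit or the low input.

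FFPE minus FF at 2 ng WT Pico called 4814 probe sets in urothelium and 1754 in BC57. A larger replicate spread in urothelium was argued against by the spreads themselves, compared after the results were seen. At FF 2 ng the root mean square SD between replicates was 0.118 in urothelium and 0.136 in BC57. At FFPE 2 ng it was 0.205 and 0.192. The test fixed beforehand took the SD of the change over probe sets, less error variance and after quantile normalization. It was 1.46 times as large in urothelium (1.41 to 1.53 without single arrays). As deposited, removing the error variance took that SD only from 0.848 to 0.837 in urothelium and from 0.613 to 0.598 in BC57. The ratio therefore largely restates the larger changes in urothelium. The narrower distribution of urothelium FFPE arrays was argued against as the whole cause, but not excluded. The ratio of calls that argues against it, and its bounds, were chosen after the values were seen. After quantile normalization 2402 and 929 were called, 2.59 times as many in urothelium (2.43 to 2.93 without single arrays) against 2.74 times as deposited. Centring, which leaves the width of the distributions, gave 4321 and 2456, a smaller excess. At 0.5 ng centring gave 4482 and 3779. The count of differing probe sets, the test fixed beforehand, decided nothing: it was 1477 as deposited and 781 after quantile normalization, 52.9% as many, and the range without single arrays (48.3% to 60.9%) spans the bound of 50%. The tissue itself, which the design names as a difference between the groups, may respond differently to fixation, and this was not tested.

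Almost no probe set was called between 0.5 ng and 2 ng within WT Pico. Too little power was argued against for changes of 2.5-fold in the measured values. Of those simulated with these replicate spreads, 100% were recovered in the FF comparison and 93.5% in the FFPE comparison. Changes between 2-fold and 2.5-fold were not simulated. Smaller changes stay open, since 65 probe sets in FF and 433 in FFPE passed the adjusted p without the size threshold. The unadjusted p was passed by 1871 and 5710, where chance gives 1062. The median of all probe sets was itself shifted at 0.5 ng, by 0.07 in FFPE (0.0165 after centring) and 0.0041 in FF. Of the 433 in FFPE 75.5% were higher, and of the 65 in FF 3.08%. The FFPE counts therefore do not separate changes of single probe sets from a shift of whole arrays.

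Other regroupings of the same arrays tested whether chance alone gives as many calls. For BC57 minus urothelium, 6 arrays make 10 splits, too few for a share under 0.05: the real split called 3180 at FF 2 ng, 3184 at FF 0.5 ng, 1562 at FFPE 2 ng and 955 at FFPE 0.5 ng, and the highest other split 0 in each; 1 of the 10 splits, the real one, gave as many. For FFPE minus FF, 1 of 100 splits within cell types, the real one, gave as many. The real count and the highest other were 2275 and 956 at 2 ng, and 3862 and 1286 at 0.5 ng. This argues against chance in the spread between these arrays only. Mixed splits carry the FFPE and FF difference in their spread, and the arrays were treated as repeat amplifications. Chance between samples was therefore not tested. For 0.5 ng minus 2 ng, 1 of 100 splits, the real one, also gave as many, with 2 and 0 in FF and 3 and 1 in FFPE. The FF count stayed at 2 without each of the 12 arrays and became 0 after quantile normalization. A count of 2 against 0 is too small to decide, and leaving out arrays is no test of chance. Chance is therefore not taken as excluded for the FF count. The FFPE count fell to 0 when any 1 of 6 among the 12 arrays was left out, so chance is not taken as excluded for it.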

How the results depend on the processing

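The use of 2 of 3 arrays per group was chosen after the data were seen; all other alternatives were fixed before the data were examined. No called change of a named probe set changed sign under the alternatives run for it, and 298 of 301 such values kept their side of the threshold. Named probe sets were not refitted with 2 arrays per group, and ENSMUSG00000056457 is not among the brighter probe sets. The other 3 were the change of ENSMUSG00000056457 at FFPE 0.5 ng without single arrays. A count is taken as kept within 1.5 times, a recall, share of calls, r or ratio within its jackknife SE. That SE is made from the values without single arrays, so it can hardly judge those values, and a less stable measure gets a wider bound. Without the eBayes trend all 39 summary values were kept. Where values moved the cause was not tested, except that the brighter set has fewer probe sets and the adjusted p alone has no size threshold.

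With all 32 arrays in 1 fit, 38 of 39 values were kept; FFPE 0.5 ng minus FFPE 2 ng called 9. After centring, 38 were kept; FFPE 0.5 ng recall was 26.2%. With array weights, 36 were kept; the share of calls also in the reference was 83.8% at FF 2 ng and 82.7% at FF 0.5 ng, and r at FF 0.5 ng was 0.948. Where at least 3 pairs could be checked, replicate numbers did not pair the arrays: in 0 of 12 comparisons did every array correlate best with its own number. Over all comparisons, correlations of same-numbered deviations ran from -0.461 to 0.293. With the replicate number as a replicate block, 38 of 39 values were kept and FFPE 0.5 ng minus FFPE 2 ng called 0. With 2 arrays per group, 7 of 8 were kept and FFPE 0.5 ng recall was 22.7%.

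Quantile normalization moved 19 of 39 values. It called 1452 for BC57 minus urothelium at FFPE 0.5 ng, and for condition contrasts 445 (FF 0.5 ng minus FF 100 ng), 676 (FFPE 50 ng minus FF 100 ng), 1281 (FFPE 2 ng minus FF 2 ng), 1901 (FFPE 0.5 ng minus FF 0.5 ng) and 0 (FF 0.5 ng minus FF 2 ng). Interactions with the reference were 670 at FFPE 2 ng and 723 at FFPE 0.5 ng. Recall was 83.5% at FFPE 50 ng, 54.0% at FFPE 2 ng and 41.2% at FFPE 0.5 ng. The share of calls also in the reference was 83.6% at FF 2 ng, 74.3% at FFPE 50 ng, 69.3% at FFPE 2 ng and 74.7% at FFPE 0.5 ng. Median ratios were 0.968, 0.669 and 0.566 in the 3 FFPE conditions, and r at FFPE 0.5 ng was 0.772.

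Among probe sets brighter than the median, 18 of 51 values moved. FFPE 0.5 ng minus FF 0.5 ng called 2049, FFPE 0.5 ng minus FFPE 2 ng 1, and the interactions 97 at FF 2 ng and 175 at FFPE 50 ng. The share of FF 2 ng calls also in the reference was 86.7%. Recall was 83.3%, 42.2% and 30.1% and the ratio 0.938, 0.503 and 0.411 at FFPE 50, 2 and 0.5 ng. Values of r were 0.967 at FF 2 ng, 0.966 at FF 0.5 ng, and 0.949, 0.847 and 0.820 in the FFPE conditions. The median SD between replicates in urothelium was 0.0525 at FF 100 ng and 0.0669 at FF 2 ng, against 0.0591 and 0.0753 over all probe sets.

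At adjusted p alone 28 of 39 values moved. BC57 minus urothelium called 10758 at FF 100 ng, 12097 at FF 2 ng, 9318 at FF 0.5 ng, 9318 at FFPE 50 ng, 8213 at FFPE 2 ng and 3468 at FFPE 0.5 ng. Condition contrasts called 9698 (FF 2 ng minus FF 100 ng), 7755 (FF 0.5 ng minus FF 100 ng), 14268 (FFPE 50 ng minus FF 100 ng), 18254 (FFPE 2 ng minus FF 2 ng), 17804 (FFPE 0.5 ng minus FF 0.5 ng), 13931 (FFPE 2 ng minus FFPE 50 ng), 65 (FF 0.5 ng minus FF 2 ng) and 433 (FFPE 0.5 ng minus FFPE 2 ng). Interactions were 1228, 376, 2172, 5214 and 3773 and recall 86.6%, 76.5%, 73.5%, 54.2% and 28.2% at FF 2 ng, FF 0.5 ng, FFPE 50 ng, FFPE 2 ng and FFPE 0.5 ng. The share of calls also in the reference was 77.0%, 88.4%, 84.8% and 70.9% in the first 4 of these.

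Without single arrays 345 of 358 values were kept. For recall, share of calls, r and ratio this was largely fixed by the rule, whose bound comes from the same values. The count kept is therefore no test of how stable these are. The FFPE 0.5 ng minus FFPE 2 ng count ran from 0 to 3, r from 0.947 to 0.951 at FF 0.5 ng and from 0.909 to 0.918 at FFPE 50 ng, and the share of FF 2 ng calls in the reference from 84.2% to 85.4%. Arrays give no depth; by brightness, recall at FFPE 0.5 ng was 6.08% of the 263 reference calls in the dim tertile, 14.6% of 1277 in the middle and 35.3% of 1733 in the bright tertile.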

Other observations

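The comparison in this part was chosen after the results were seen, and no explanation is offered for it. WT Pico at 2 ng was set against a kit of higher input once in FF RNA and once in FFPE RNA, in contrasts that share no arrays. The changes correlated at r = 0.340 over probe sets, with 212 probe sets called in the same direction in both, 27 in opposite directions and 20.9 for independent lists. After quantile normalization r was 0.397, with 170 shared, 12 opposite and 12.1 for independent lists. ENSMUSG00000056457 was lower under WT Pico than in the other kit in BC57, at 6.47 ± 0.11 (SD, n = 3) at FF 2 ng against 9.67 ± 0.07 (n = 2) in the reference, and at 3.28 ± 1.02 (n = 3) at FFPE 2 ng against 9.85 ± 0.22 (n = 2) at FFPE 50 ng; these differences between conditions were not tested for this probe set alone.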
